A study of Homo sapiens with 12 samples.

How the data were processed

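RNA from OCI-AML2 cells with a control guide (sgLuc) or a KDM6A guide (sgUTX_2 or sgUTX_4), each with DMSO or 1 µM SGC0946 for 6 days, was sequenced in 12 libraries, 2 for each of the 6 combinations. The deposited table holds raw read counts per gene, not normalized, for 58735 Ensembl gene identifiers. Per the labels' protocols the libraries were made from total RNA and read as pairs of 150 bases. Per the submitters' processing notes, STAR 2.5.1b and the genome build hg19 were used. The identifiers in the deposited count table are exactly the 58735 of GENCODE 29, an annotation of GRCh38, so the build on which the counts were made is uncertain, and the KDM6A position is given from GENCODE 29. The counting program, its use of strand and its treatment of reads that fit several genes are not given in the sources used here, nor are the guide sequences. Reads of near-identical genes (HLA, Fc receptor and LILR families) can therefore be split or lost, and reads of overlapping genes cannot be told apart. Among genes named in the text, IFITM1 shares 32.5% of its exonic bases with IFITM2, CCNE2 37% with INTS8, SERPINB2 19.9% with SERPINB10, CIITA 11.6% with DEXI and ASNS 44.6% with a clone-named gene.

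Groups came from the labels of each sample. Total counts per library lay between 15480493 and 23262141. No columns were identical, and the chi-square per gene between the 2 libraries of a group lay between 2.85 and 6.29 over genes with at least 20 counts, above the value of 1 that sampling alone gives, so all 12 were kept as separate libraries. Intervals and p-values cover the spread between these libraries.

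Counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr, robust quasi-likelihood F-tests, two-sided), and adjusted p-values are Benjamini-Hochberg values over the 15060 genes kept, called at under 0.05. Adjusted p-values of genes come from this test unless another is named. All 12 libraries were fitted together in 4 groups (control or sgUTX, DMSO or SGC0946), so that the 2 guides counted as replicates and their difference entered the error (8 residual degrees of freedom, common biological coefficient of variation 0.0775). The 5 contrasts were sgUTX against control in each treatment, SGC0946 against DMSO in each genotype, and the difference of the 2 responses. A fit of 6 groups (6 residual degrees of freedom, 0.057) gave each guide its own mean for comparisons of single guides. Standard errors were computed from the fold change and its F value. CPM values are scaled by TMM factors, which were 0.854 and 0.888 for the control DMSO, 0.924 and 0.934 for the control SGC0946 and 1.03 to 1.07 for the sgUTX libraries.

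The groups, tests, alternatives, 24 gene lists and the rule for named genes were set before the data were examined. Lists were MLL fusion targets, the HOXB cluster, monocyte and macrophage differentiation, granule and neutrophil genes, stem and progenitor genes, cell cycle and DNA replication, CDK inhibitors and D cyclins, p53 targets, the BCL2 family, MHC class II and class I presentation, interferon-stimulated genes, UTX partners with H3K4 and H3K27 enzymes, cholesterol synthesis, MYC and ribosome biogenesis, glycolysis, the integrated stress response, MAPK feedback and immediate early genes, nucleoside analogue uptake and metabolism, drug efflux pumps, and erythroid, megakaryocyte, lymphoid and adherent cell markers. Lists with at least 3 measured members were tested with camera (limma 3.58.1, preset inter-gene correlation 0.01), adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Of the 51 list calls 8 held with an estimated correlation. Counts of list members are over all genes tested, and those adjusted over the list alone were the same unless given.

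The rule named, per comparison, the 12 genes with the largest rise and fall among called genes with an average log2 CPM of at least 1 and libraries that did not overlap, leaving out clones, pseudogenes, small, antisense and long intergenic transcripts and Y-linked genes and XIST, together with the 2 to 4 list members of smallest adjusted p, KDM6A and KDM6B. The text names a part of these genes, chosen after their values were seen, and left out genes with at most 3 counts in a compared group. Results of 2 single genes are not reported here. A few genes outside the rule appear in the closing section and are said there to be chosen after their values were seen. All named genes and lists are human symbols of GENCODE 29, and 2 list symbols, older names of genes already listed, matched no identifier of their own.

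The fits were tested on simulated counts in which all libraries shared the real mean of each gene. Of the genes with a mean of at least 1 CPM, 200 were changed, some up and some down. At 2-fold, 91% of changed genes were recovered for sgUTX against control in DMSO (14556 genes), 83.6% for SGC0946 in control cells (14529), 94% in sgUTX cells (14531), 83.6% for sgUTX against control in SGC0946 (14541) and 79.1% for the response difference (14542), with 4 to 13 calls among unchanged genes. At 1.5-fold the recovered shares were 71.6%, 73.1%, 82.1%, 67.2% and 58.2%. The simulation held no guide difference and few changed genes, so these shares need not carry over to the real data, where far more genes were called.

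Alternatives were DESeq2 1.42.0, RLE factors, library size only, no low-count filter, a filter of at least 1 CPM in at least 4 libraries, the 6-group fit, only the libraries compared, each guide alone, the replicate number as a block, a 2-fold threshold and leaving out each library. Scaling on genes other than ribosomal protein, histone and mitochondrial genes was added after the data were seen. Overlaps of the guides were set against 20 simulations of unchanged guides and against n1 × n2 / N of independent lists.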

Results

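RNA was sequenced from OCI-AML2, a human acute myeloid leukemia line that carries a rearranged KMT2A (MLL) gene. Cells carried the control guide sgLuc, directed at luciferase, or 1 of 2 guides (sgUTX_2, sgUTX_4) against KDM6A, the gene of the histone H3K27 demethylase UTX. They were grown for 6 days with DMSO or with 1 µM SGC0946, an inhibitor of the histone methyltransferase DOT1L. Each of the 6 combinations of guide and treatment had 2 libraries, so that each treatment held 2 control and 4 sgUTX libraries, 12 libraries in all. Total counts per library ranged from 15480493 to 23262141, and 15060 genes were tested. The labels did not state that libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

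On the log2 CPM scale, principal component 1 held 53.4% and component 2 held 23.1% of the variance. The sgUTX libraries in DMSO lay between 52.6 and 58.2 on component 1, and those with SGC0946 between 7.8 and 9.6. Control libraries with SGC0946 lay at -96.1 and -99.8. The control DMSO libraries stood apart on component 2, at 67.6 and 75.0, with every other library below 9.1. In the control DMSO libraries, genes of cytoplasmic ribosomal proteins took 17.7% and 18.9% of all counts, against 12.9% to 13.1% in control SGC0946 libraries and 10.97% to 12.12% in the 8 sgUTX libraries.

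**Figure D1:**
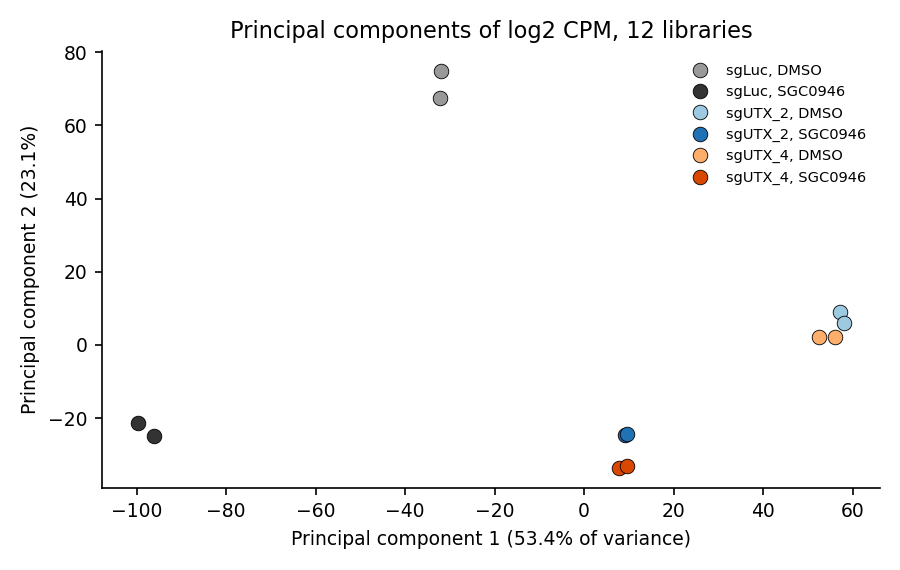
Principal components 1 (horizontal, 53.4% of variance) and 2 (vertical, 23.1%) of log2 CPM, 1 point per library and 1 color per guide and treatment. The 2 control DMSO libraries sit alone at the top, at 67.6 and 75.0 on component 2.

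KDM6A (ENSG00000147050), the targeted gene, lies at X:44873177-45112602 on the plus strand (GRCh38, GENCODE 29). Its transcript was lower with sgUTX_2 and higher with sgUTX_4 than with sgLuc. In DMSO it stood at 30.0 ± 2.91 CPM with sgLuc, 15.1 ± 0.618 with sgUTX_2 and 47.8 ± 2.26 with sgUTX_4 (mean ± SD, n = 2 each). With SGC0946 the levels were 34.8 ± 0.413, 15.2 ± 1.03 and 46.0 ± 4.03 CPM (n = 2 each). Against sgLuc in DMSO the log2 fold change of KDM6A was -0.99 for sgUTX_2 (SE 0.10, edgeR adjusted p = 3.56e-10) and 0.67 for sgUTX_4 (SE 0.09, adjusted p = 1.94e-07). In SGC0946 it was -1.20 (adjusted p = 1.89e-12) and 0.41 (adjusted p = 0.000301). The 4 sgUTX libraries as 1 group did not pass the test in DMSO, with a log2 fold change of 0.05 (SE 0.70, adjusted p = 0.957), and its sign changed when the 2 guides were averaged in a fit of 6 groups (-0.16). CRISPR insertions and deletions need not lower a transcript, so these levels cannot show whether UTX was lost with either guide. Directions below are therefore those of libraries labelled UTX knockout, named after the guide as sgUTX libraries.

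**Figure D2:**
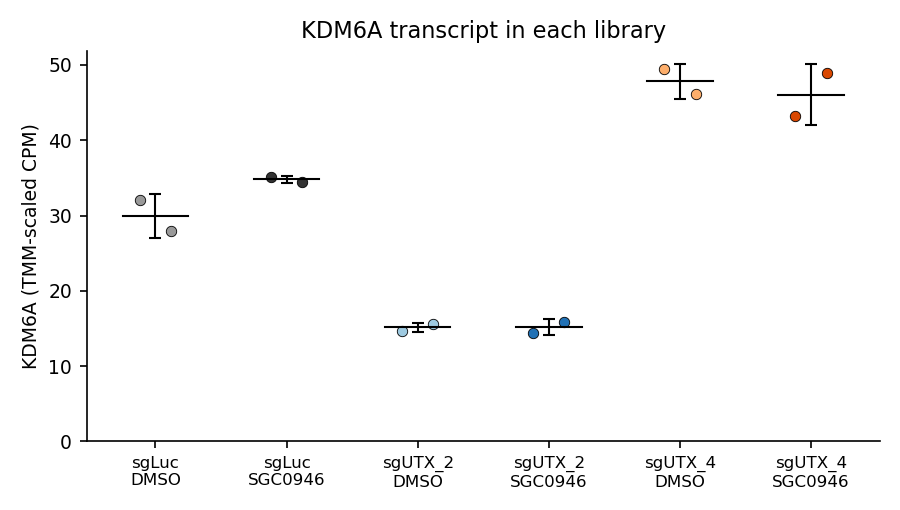
KDM6A transcript level (TMM-scaled CPM, vertical axis) in each of the 12 libraries by guide and treatment, with a line for the mean and bars for the SD of the 2 libraries. The sgUTX_2 libraries lie below and the sgUTX_4 libraries above the sgLuc libraries in both treatments.

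The 2 guides gave largely overlapping sets of called genes. In DMSO, 3733 genes were higher and 4225 lower than control with both guides, where independent lists would share 1212 and 1514, and 12 genes were called in opposite directions. With SGC0946, both guides had 3513 genes higher and 3837 lower (1122 and 1272 for independent lists), with 6 in opposite directions. Across 11704 genes, which are not independent replicates, fold changes of the guides correlated at 0.952 in DMSO and 0.967 with SGC0946. Simulated unchanged guides, with all libraries drawn from the control means, gave mean correlations of 0.525 and 0.513, and at most 1 gene called for both. The simulation holds no difference of the control population from the others, so it cannot speak on that. The covariance was 0.731 in DMSO and 0.676 with SGC0946, against 0.0118 and 0.0114 in simulation. Part of the shared calls may come from the shared controls, since 2 control libraries per treatment cannot be split with 2 on each side. With no library in common, sgUTX_2 in DMSO and sgUTX_4 in SGC0946 still correlated at 0.71, and the reverse pairing at 0.656.

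Between the guides, 526 genes differed in DMSO (259 higher with sgUTX_4) and 454 with SGC0946 (243 higher). KDM6A itself differed by 1.66 (adjusted p = 7.05e-14) and 1.60 on the log2 scale. The counts rested on single libraries. The DMSO count was 89 without the first sgUTX_4 DMSO library and 274 without the second sgUTX_2 DMSO library. With SGC0946 it was 90 without the first sgUTX_4 library, and 102 or 283 without the first or second sgUTX_2 library.

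The first comparison asks how cells with UTX guides differ from control cells in the absence of the inhibitor. Glycolysis and antigen presentation genes were lower in sgUTX than in control DMSO libraries (values below are mean CPM ± SD, n = 2 control and 4 sgUTX libraries). Of 20 measured glycolysis genes, 17 were lower and 1 was higher, with a median log2 fold change of -0.94 (camera adjusted p = 9.1e-15; adjusted p = 0.0155 with an estimated correlation). PFKFB4, a kinase that sets the level of a phosphofructokinase activator, dropped from 198 ± 5.66 to 5.60 ± 0.438 CPM (log2 fold change -5.14, SE 0.10, adjusted p = 7.8e-19). The glycolytic enzymes ENO2, GPI and LDHA had log2 fold changes of -4.49, -1.55 and -1.32, and LDHA went from 2080 ± 129 to 833 ± 38.8 CPM. Among 11 MHC class II presentation genes, 8 were lower and 2 higher, with a median of -3.33 (camera adjusted p = 6.69e-06; adjusted p = 0.0619 with an estimated correlation). HLA-DRA went from 59.8 ± 2.95 to 1.21 ± 0.372 CPM (-5.63, SE 0.29), HLA-DPA1 changed by -5.51, its transactivator CIITA by -3.75 and the invariant chain CD74 by -1.78. HLA genes are close copies of one another, and CIITA shares exonic bases with DEXI, so their single values are uncertain.

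Interferon-stimulated genes were also lower in sgUTX DMSO libraries, 17 of 25 against 1 higher (median -1.36, camera adjusted p = 7.56e-05; adjusted p = 0.0474 with an estimated correlation). The antiviral enzyme OAS2 went from 11.9 ± 0.054 to 0.958 ± 0.387 CPM (-3.65), and STAT2 and IFI6 changed by -1.23 and -1.86. MHC class I presentation genes were lower in 10 and higher in 2 of 13 (camera adjusted p = 0.00491; adjusted p = 0.0619 with an estimated correlation), with HLA-E at -1.28 and HLA-B at -1.0. Of 20 cholesterol synthesis genes 18 were lower and 1 was higher (median -1.03, camera adjusted p = 0.000195; adjusted p = 0.46 with an estimated correlation), among them STARD4 (-1.46), IDI1 (-1.30) and MVD (-1.18). Monocyte and macrophage differentiation genes were lower in 13 and higher in 1 of 23 (median -0.80, camera adjusted p = 7.4e-05; adjusted p = 0.304 with an estimated correlation). The costimulatory ligand CD86 went from 9.16 ± 0.107 to 0.799 ± 0.161 CPM (-3.5), and LGALS3 changed by -2.43. CYBB, the catalytic subunit of the phagocyte oxidase, was the member that rose, from 150 ± 7.46 to 355 ± 19.5 CPM (1.24). Of 9 lymphoid markers 7 were lower (camera adjusted p = 0.00469; adjusted p = 0.0619 with an estimated correlation), and CD4, which monocytes also carry, changed by -1.49.

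Integrated stress response, ribosome biogenesis and replication genes were higher in sgUTX DMSO libraries. Of 19 integrated stress response genes 13 were higher and 2 lower (median 1.06, camera adjusted p = 1.5e-05; adjusted p = 0.154 with an estimated correlation). CHAC1, which degrades glutathione, rose from 9.22 ± 0.513 to 57.5 ± 5.46 CPM (2.63, SE 0.13, adjusted p = 8.6e-14), the cystine transporter SLC7A11 by 2.69, the amino acid transporter SLC7A5 by 1.76 and the pseudokinase TRIB3 by 1.43. SLC7A2, a transporter of cationic amino acids outside that list, rose by 2.91. Of 25 cell cycle and DNA replication genes 14 were higher and 5 lower (median 0.82, camera adjusted p = 5.15e-07; adjusted p = 0.0619 with an estimated correlation), including the helicase subunits MCM3 (1.30) and MCM6 (1.24), CDC6 (1.47) and E2F1 (1.77). CCNE2, a cyclin of S phase entry, rose by 2.57, and shares exonic bases with INTS8 on the other strand. MYC and ribosome biogenesis genes were higher in 15 and lower in 3 of 20 (median 0.74, camera adjusted p = 1.58e-05; adjusted p = 0.12 with an estimated correlation), with RRP12 at 1.25 and NOP56 at 0.84. The counts taken by ribosomal protein genes were higher in the control DMSO libraries (17.7% and 18.9%) than in the 4 sgUTX DMSO libraries (11.1% to 11.9%).

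Genes of UTX's own complexes and of histone H3K4 and H3K27 enzymes were higher in 15 and lower in 2 of 22 (median 0.47, camera adjusted p = 0.000463; adjusted p = 0.0619 with an estimated correlation), and in 19 and 1 with library size only (median 0.75). This list also holds DOT1L, the target of SGC0946. EZH2, the H3K27 methyltransferase, rose by 1.43 and SETD1B by 1.39. KDM6B, the other H3K27 demethylase gene, went from 129 ± 2.54 to 95.9 ± 2.94 CPM (-0.43, adjusted p = 4.7e-06), and did not pass with library size only (-0.15, adjusted p = 0.0578). Of 18 MLL fusion targets 8 were lower and 3 higher, and the list was not called (camera adjusted p = 0.266), with HOXA10 at -0.93, PBX3 at -0.72 and HOXA9 at -0.66. For p53 targets 7 were higher and 7 lower of 19 (camera adjusted p = 0.432; 9 and 7 adjusted over the list alone), with AEN at 1.91 and BTG2 at -2.39. Among the largest fold changes were those of JPH2, a protein that joins membranes, from 63.4 ± 3.11 to 0.0684 ± 0.085 CPM (-9.60, SE 0.27), and PNCK, a calmodulin-dependent kinase, from 8.13 ± 1.44 to 0.0658 ± 0.132 CPM (-6.65, SE 0.65). Both rest on 6 counts over the 4 sgUTX libraries. The peptide hormone gene ADM changed by -5.94, the creatine transporter SLC6A8 by -5.73 and GPNMB by -5.37, while the integrin ITGAV rose by 3.46 and the transcription factor EGR1 by 2.74. PECAM1, an adhesion molecule of the adherent cell marker list, changed by -2.59, and that list was not called (2 of 8 lower, camera adjusted p = 0.122).

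In all, 4325 genes were higher and 4863 lower in sgUTX than in control DMSO libraries by edgeR's quasi-likelihood test (adjusted p under 0.05), 1033 and 2034 of them by at least 2-fold. With library size only, 66.7% of the called genes were higher, against 47.1% with TMM scaling, and the median of all genes moved from -0.01 to 0.26 on the log2 scale.

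The second comparison asks what DOT1L inhibition does to control cells (n = 2 and 2). MLL fusion targets fell and monocyte genes rose in control cells with SGC0946. Of 18 MLL fusion targets 16 fell and 1 rose, with a median log2 fold change of -1.51 (camera adjusted p = 7.06e-26; adjusted p = 0.000106 with an estimated correlation). MEIS1, a homeobox partner of HOXA proteins, went from 39.9 ± 1.55 to 1.32 ± 0.774 CPM (-4.93, SE 0.25, adjusted p = 9.5e-12). HOXA5 changed by -3.23, RUNX2 by -2.97, PBX3 by -2.77 and the kinase CDK6 by -2.12, from 217 ± 7.31 to 49.9 ± 1.48 CPM. BCL2, an anti-apoptotic gene of that list, changed by -1.35. Of 23 monocyte and macrophage differentiation genes 22 rose and 1 fell, with a median of 3.09 (camera adjusted p = 2.22e-23; adjusted p = 0.0577 with an estimated correlation). CYBB rose from 150 ± 7.46 to 997 ± 32.1 CPM (2.73, SE 0.09), CD86 by 3.73 and the Fc receptor FCGR3A by 6.27.

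Granule and neutrophil genes rose in 11 and fell in 2 of 17 in control cells with SGC0946 (median 2.51, camera adjusted p = 0.000183; adjusted p = 0.344 with an estimated correlation), with CEBPE, a regulator of granulocyte maturation, at 1.55, the antimicrobial peptide gene CAMP at 5.48 and the formyl peptide receptor FPR1 at 6.75. Among the largest rises, FCGR3B went from 0.176 ± 0.0726 to 111 ± 6.47 CPM (9.29, SE 0.30), VNN2 from 0.131 ± 0.0785 to 73.1 ± 9.43 (9.0, SE 0.31), LILRA5 changed by 8.48 and the chemokine receptor CXCR1 by 6.89. FCGR3B, VNN2, CXCR1 and LILRA5 had only 5, 4, 5 and 5 counts over the 2 control DMSO libraries, and FCGR3A and FCGR3B, like the LILR genes, are near-identical copies whose reads can be split. Among the large falls were those of MMRN1 (-5.76), SOCS2, a brake on cytokine signaling, from 91.0 ± 1.37 to 2.26 ± 0.0537 CPM (-5.33, SE 0.14), and DACH1 (-3.27).

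Of 11 MHC class II genes 8 rose and 1 fell in control cells with SGC0946 (median 1.70, camera adjusted p = 0.00619; adjusted p = 0.264 with an estimated correlation), HLA-DMB by 3.45 and HLA-DPA1 by 1.92. Interferon-stimulated genes rose in 14 and fell in 2 of 25 (15 and 2 adjusted over the list alone; camera adjusted p = 0.0119; adjusted p = 0.167 with an estimated correlation). OAS3 rose by 4.04 and IFITM1 by 2.45, the second sharing exonic bases with IFITM2. For p53 targets 11 rose and 3 fell of 19 (camera adjusted p = 0.0109; adjusted p = 0.167 with an estimated correlation). The CDK inhibitor CDKN1A rose from 16.7 ± 0.863 to 74.2 ± 2.33 CPM (2.15, SE 0.12) and BTG2 by 1.39. Of 21 MAPK feedback and immediate early genes 10 rose and 2 fell (11 and 2 adjusted over the list alone; camera adjusted p = 0.0183; adjusted p = 0.264 with an estimated correlation), with JUN at 2.27 and IER3 at 2.13. The list of CDK inhibitors and D cyclins was not called (camera adjusted p = 0.817), and its member CCND3 rose by 1.26.

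MYC and ribosome biogenesis genes fell in 10 and rose in 2 of 20 (camera adjusted p = 0.0152; adjusted p = 0.344 with an estimated correlation). MYC went from 785 ± 27.1 to 346 ± 5.80 CPM (-1.18, SE 0.07), and the nucleolar genes NPM1 and FBL changed by -0.85 and -0.78. Ribosomal protein genes took 17.7% and 18.9% of counts in the DMSO and 12.9% to 13.1% in the SGC0946 libraries of control cells. Integrated stress response genes fell in 13 and rose in 2 of 19 (camera adjusted p = 0.0131; adjusted p = 0.351 with an estimated correlation), with CHAC1 at -1.89 and DDIT4 at -1.22. Cell cycle and DNA replication genes were not called as a list (13 of 25 higher, 5 lower, camera adjusted p = 0.0622), though MKI67 rose by 1.11 and PCNA by 0.83. SAMHD1, which hydrolyzes deoxynucleotides, rose by 2.34 and RRM2, a ribonucleotide reductase subunit, by 1.76, and their list of nucleoside analogue genes was not called (camera adjusted p = 0.0737). Within the BCL2 family (5 of 14 higher, 2 lower, camera adjusted p = 0.229), BCL2A1 rose by 1.63. KDM6B stood at 129 ± 2.54 and 136 ± 2.37 CPM and did not pass (0.08, adjusted p = 0.40). In all, 3725 genes rose and 3641 fell in control cells by edgeR's quasi-likelihood test, 1487 and 719 by at least 2-fold. With library size only, 60.9% of the called genes were higher, against 50.6%.

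The third comparison is the same treatment in sgUTX cells (n = 4 and 4). MLL fusion targets fell there too, and monocyte and MHC class II genes rose. Of 18 MLL fusion targets 17 fell and 1 rose, with a median of -1.11 (camera adjusted p = 4.42e-39; adjusted p = 1.75e-05 with an estimated correlation). MEF2C, a transcription factor of myeloid progenitors, went from 373 ± 20.8 to 86.2 ± 7.57 CPM (-2.11, SE 0.06, adjusted p = 3.2e-17). HOXA5 changed by -3.25, MEIS1 by -2.16, and CDK6 and SATB1 by -1.11 each. Of 11 MHC class II genes 9 rose and none fell (median 2.79, camera adjusted p = 8.51e-12; adjusted p = 0.0348 with an estimated correlation). HLA-DPA1 rose from 0.273 ± 0.0784 to 5.02 ± 1.26 CPM (4.17, SE 0.27), HLA-DRB1 by 3.95, HLA-DMB by 3.71 and CD74 by 0.84. Of 23 monocyte and macrophage differentiation genes 16 rose and 1 fell (17 and 1 adjusted over the list alone; median 1.12, camera adjusted p = 7.44e-16; adjusted p = 0.0711 with an estimated correlation). CD86 rose from 0.799 ± 0.161 to 4.77 ± 0.665 CPM (2.57) and the protease CTSD by 0.69, while FCGR1A was the member that fell (-1.09).

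Integrated stress response genes fell in 15 and rose in 1 of 19 in sgUTX cells (17 and 1 adjusted over the list alone; camera adjusted p = 1.07e-11; adjusted p = 0.0703 with an estimated correlation), with TRIB3 at -1.26, ATF3 at -1.22 and CHAC1 at -1.04. Cholesterol synthesis genes rose in 17 of 20 (median 0.62, camera adjusted p = 1.12e-05; adjusted p = 0.374 with an estimated correlation), STARD4 by 0.73 and IDI1 by 0.68. Granule and neutrophil genes rose in 11 and fell in 2 of 17 (median 1.35, camera adjusted p = 3.91e-05; adjusted p = 0.335 with an estimated correlation). With 1 member that had no counts in a group set to its bound (3 counts over the group), the median was 1.33. The matrix protease MMP9 rose by 4.03 and FPR1 by 2.52. Of 21 MAPK feedback and immediate early genes 9 fell and 3 rose (camera adjusted p = 0.0113; adjusted p = 0.187 with an estimated correlation), and EGR1 went from 42.8 ± 6.58 to 9.71 ± 1.25 CPM (-2.14). Of 13 CDK inhibitors and D cyclins 7 fell and 1 rose (8 and 2 adjusted over the list alone; camera adjusted p = 0.0289; adjusted p = 0.138 with an estimated correlation), and CDKN1A went from 11.4 ± 0.946 to 7.19 ± 0.831 CPM (-0.66). MYC and ribosome biogenesis genes fell in 6 of 20 (camera adjusted p = 0.0474; adjusted p = 0.388 with an estimated correlation). Of 8 adherent cell markers 4 rose (median 1.82, camera adjusted p = 0.00239; adjusted p = 0.0711 with an estimated correlation), among them PECAM1 (1.33), which leukocytes also carry.

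Among the leading rises in sgUTX cells were SERPINB2 (5.55) and SERPINB10 (4.59), protease inhibitor genes that share exonic bases with each other, the endosomal receptor TLR8 (4.24), properdin CFP (4.23) and FGL2, from 3.16 ± 0.422 to 52.0 ± 3.08 CPM (4.03, SE 0.09). Among the falls were the serotonin receptor HTR1F (-3.39), MMRN1 (-2.43) and SOCS2 (-2.08). SAMHD1 rose by 1.37, and KDM6B went from 95.9 ± 2.94 to 69.6 ± 4.87 CPM (-0.46, adjusted p = 3.9e-07). In all, 2626 genes rose and 2471 fell by edgeR's quasi-likelihood test, 962 and 154 by at least 2-fold.

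**Figure D3:**
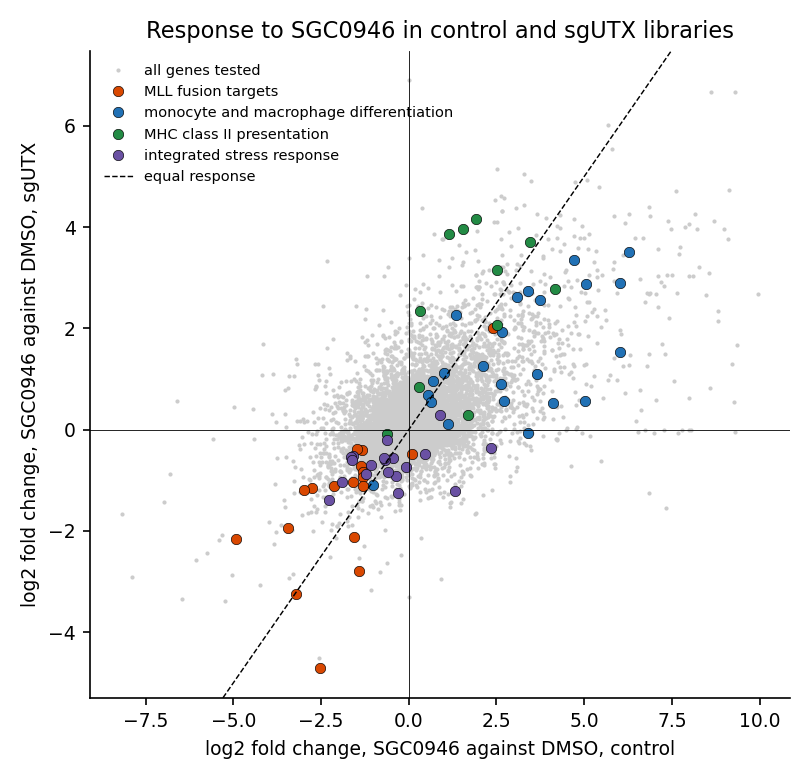
Log2 fold change after SGC0946 in control (horizontal) and sgUTX libraries (vertical), 1 point per gene, with 4 gene lists in color and a dashed line for equal responses. Most monocyte genes lie below the dashed line (medians 3.09 and 1.12), while most MLL fusion targets lie below 0 on both axes (medians -1.51 and -1.11).

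The fourth comparison asks how sgUTX and control cells differ once DOT1L is inhibited (n = 2 control and 4 sgUTX libraries). All 23 monocyte and macrophage differentiation genes were lower in sgUTX than in control SGC0946 libraries, with a median of -2.35 (camera adjusted p = 2e-24; adjusted p = 0.0356 with an estimated correlation). CD86 stood at 122 ± 9.76 CPM in control and 4.77 ± 0.665 in sgUTX libraries (-4.67, SE 0.10, adjusted p = 1.1e-19), and the protease CTSB differed by -1.58. Interferon-stimulated genes were lower in 19 of 25 (median -1.54, camera adjusted p = 4.23e-09; adjusted p = 0.0198 with an estimated correlation), with OAS2 at -4.13 and IRF7 at -2.27. Glycolysis genes were lower in 17 of 20 (median -0.63, camera adjusted p = 1.29e-08; adjusted p = 0.0356 with an estimated correlation), with PFKFB4 at -3.37, the glucose transporter SLC2A3 at -2.96 and ENO2 at -2.55.

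MHC class II genes were lower in 9 and higher in 1 of 11 sgUTX against control in SGC0946 (median -2.16, camera adjusted p = 1.45e-05; adjusted p = 0.0539 with an estimated correlation), with CD74 at -1.25. Cholesterol synthesis genes were lower in 18 of 20 (camera adjusted p = 0.00094; adjusted p = 0.444 with an estimated correlation), with STARD4 at -1.29. Granule and neutrophil genes were lower in 8 and higher in 3 of 17 (camera adjusted p = 0.0355; adjusted p = 0.487 with an estimated correlation). Of 21 MAPK feedback and immediate early genes 10 were lower and 1 higher (10 and 5 with library size only; camera adjusted p = 0.000803; adjusted p = 0.0702 with an estimated correlation), with FOS at -3.39, JUN at -3.36 and IER3 at -3.00. CDK inhibitors and D cyclins were lower in 8 and higher in 3 of 13 (camera adjusted p = 0.0207; adjusted p = 0.0911 with an estimated correlation). CDKN1A stood at 74.2 ± 2.33 CPM in control and 7.19 ± 0.831 in sgUTX libraries (-3.36, SE 0.10). BTG2 differed by -3.25, and p53 targets as a list were not called (5 higher and 7 lower of 19, camera adjusted p = 0.212). Lymphoid markers were lower in 6 of 9 (camera adjusted p = 0.0355; adjusted p = 0.109 with an estimated correlation). BCL2A1 differed by -2.59 and KDM6B by -0.96.

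MYC and ribosome biogenesis genes were higher in 19 of 20 in sgUTX SGC0946 libraries (median 0.69, camera adjusted p = 4.23e-09; adjusted p = 0.0539 with an estimated correlation), POLR1B by 1.07, BOP1 by 1.10 and MYC by 0.82, from 346 ± 5.80 to 612 ± 22 CPM. Integrated stress response genes were higher in 15 and lower in 4 of 19 (median 1.09, camera adjusted p = 0.000434; adjusted p = 0.239 with an estimated correlation), CHAC1 by 3.48 and the asparagine synthetase gene ASNS by 2.46. ASNS rests on low counts and shares exonic bases with a clone-named gene. The glycine transporter SLC6A9 was higher by 3.98 and SLC7A2 by 2.99. Cell cycle and DNA replication genes were higher in 13 of 25 (median 0.20, camera adjusted p = 0.00149; adjusted p = 0.239 with an estimated correlation), and in 21 with library size only (median 0.38). MLL fusion targets went both ways, 8 higher and 7 lower of 18 (8 and 8 adjusted over the list alone, 10 and 4 with library size only; camera adjusted p = 0.0812), with RUNX2 at 1.25, CDK6 at 1.16 and MYB at 0.90. Among the largest differences were VNN2 (-6.73), LILRA5 (-6.55), osteopontin SPP1, at 396 ± 50.7 and 4.97 ± 1.44 CPM (-6.32, SE 0.19), and the Fc receptors FCGR2B (-5.90), FCGR3B (-5.85) and FCGR3A (-5.70), which have close copies. In all, 4165 genes were higher and 4406 lower by edgeR's quasi-likelihood test, 745 and 1849 by at least 2-fold. With library size only, 65.0% of called genes were higher, against 48.6%, and the median of all genes was 0.20 in place of 0.01.

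**Figure D4:**
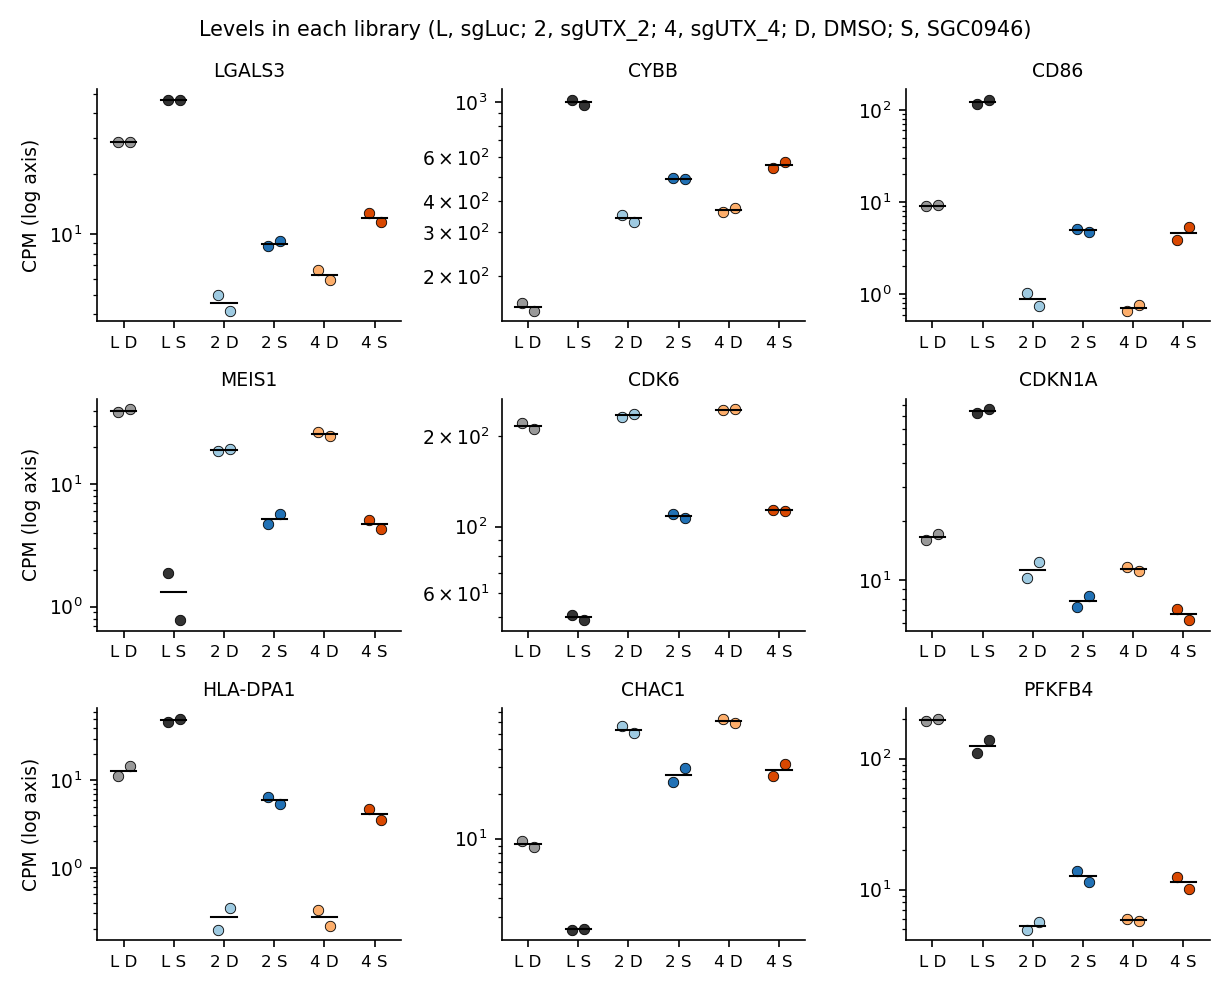
Levels of 9 genes (CPM, log axis) in each library, by guide (L, sgLuc; 2, sgUTX_2; 4, sgUTX_4) and treatment (D, DMSO; S, SGC0946), with a line for the mean of 2 libraries. CD86 rises with SGC0946 from a lower start and to a lower level with either sgUTX guide, and CDKN1A rises with sgLuc (2.15, log2) and falls with the sgUTX guides (-0.66).

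The fifth comparison is the difference between the responses to SGC0946, sgUTX minus control, tested as an interaction. Monocyte genes rose less and MLL fusion targets fell less in sgUTX than in control cells. Of 23 monocyte and macrophage differentiation genes 11 had a lower and 1 a higher response (14 and 1 adjusted over the list alone; median -1.17, camera adjusted p = 8.98e-07; adjusted p = 0.156 with an estimated correlation). CYBB rose by 2.73 in control and 0.57 in sgUTX cells, a difference of -2.16 (SE 0.10, adjusted p = 7.8e-13). CD14 rose by 6.01 and 2.90, and CTSB by 1.11 in control cells against 0.11 in sgUTX cells (adjusted p = 0.12). MPEG1 differed by -4.49 and FCN1 by -4.48, and FCN1 lost its call without the first or second control DMSO library or the second control SGC0946 library (largest adjusted p = 0.0911). MLL fusion targets had a higher response in 10 and a lower in 4 of 18 (12 and 4 adjusted over the list alone; median 0.52, camera adjusted p = 0.000183; adjusted p = 0.0547 with an estimated correlation). RUNX2 fell by 2.97 in control and by 1.18 in sgUTX cells (difference 1.79, SE 0.14), PBX3 differed by 1.61, ZEB2 by 1.09 and CDK6 by 1.01.

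MAPK feedback and immediate early genes had a lower response in 11 of 21 (12 lower and 1 higher adjusted over the list alone; median -0.71, camera adjusted p = 6.99e-06; adjusted p = 0.0547 with an estimated correlation), EGR1 by -2.48, IER3 by -2.61 and JUNB by -0.89. For p53 targets 11 were lower and 5 higher of 19 (camera adjusted p = 0.00282; adjusted p = 0.106 with an estimated correlation). CDKN1A rose by 2.15 in control cells and fell by 0.66 in sgUTX cells, a difference of -2.81 (SE 0.15, adjusted p = 5.7e-12). Its list of CDK inhibitors and D cyclins was not called (camera adjusted p = 0.0763), and CCND3 differed by -1.53. Cell cycle and DNA replication genes had a lower response in 12 and a higher in 5 of 25 (14 and 5 adjusted over the list alone; camera adjusted p = 0.00227; adjusted p = 0.204 with an estimated correlation). Genes of UTX partners and of H3K4 and H3K27 enzymes, a list that also holds DOT1L, were lower in 11 and higher in 1 of 22 (camera adjusted p = 0.00115; adjusted p = 0.106 with an estimated correlation), EZH2 by -0.90 and KDM6B by -0.54. RRM2 differed by -1.62 and BCL2A1 by -1.75.

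MHC class II genes had a higher response in 6 of 11 (median 0.55, camera adjusted p = 0.00887; adjusted p = 0.204 with an estimated correlation), HLA-DPA1 by 2.25 and CIITA by 2.03. HLA-DPA1 rose in sgUTX cells from a low start, 22 counts over the DMSO libraries. With SGC0946 it stayed below control, at 5.02 ± 1.26 against 48.7 ± 3.08 CPM. MHC class I genes were higher in 6 of 13 (7 adjusted over the list alone; camera adjusted p = 0.0309; adjusted p = 0.156 with an estimated correlation). Glycolysis genes were higher in 9 and lower in 2 of 20 (camera adjusted p = 0.00479; adjusted p = 0.156 with an estimated correlation), with PFKFB4 at 1.77. MYC differed by 1.07, and its list was not called (camera adjusted p = 0.129). Integrated stress response genes went both ways, 6 higher and 4 lower of 19, with a median of 0.10, a mean of -0.16 and no call (camera adjusted p = 0.315), and ATF3 differed by -2.52. Among the largest response differences were LILRA5 (-5.81), LILRB3 (-4.70), C5AR1, a complement receptor that rose by 4.19 in control cells (difference -4.37, SE 0.24), FPR1 (-4.23), JPH2 (4.89), EEF1A2 (3.93), NFATC4 (3.79), MMRN1 (3.34) and SOCS2 (3.25). LILRA5 has few counts in DMSO libraries of both genotypes and JPH2 in sgUTX DMSO libraries.

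In all, the response was higher in 2756 and lower in 2484 genes by edgeR's quasi-likelihood test, 665 and 669 by at least 2-fold. With library size only, 40.6% were higher, against 52.6%. Of the 3725 genes that rose and the 3641 that fell in control cells, 324 and 251 were called in the opposite direction in sgUTX cells and in the response difference. Rises in both were called for 1540 genes, where independent lists would share 650, and falls in both for 1238, against 597. With no library in common, the 2 responses correlated at 0.657 across 11704 genes.

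**Figure D5:**
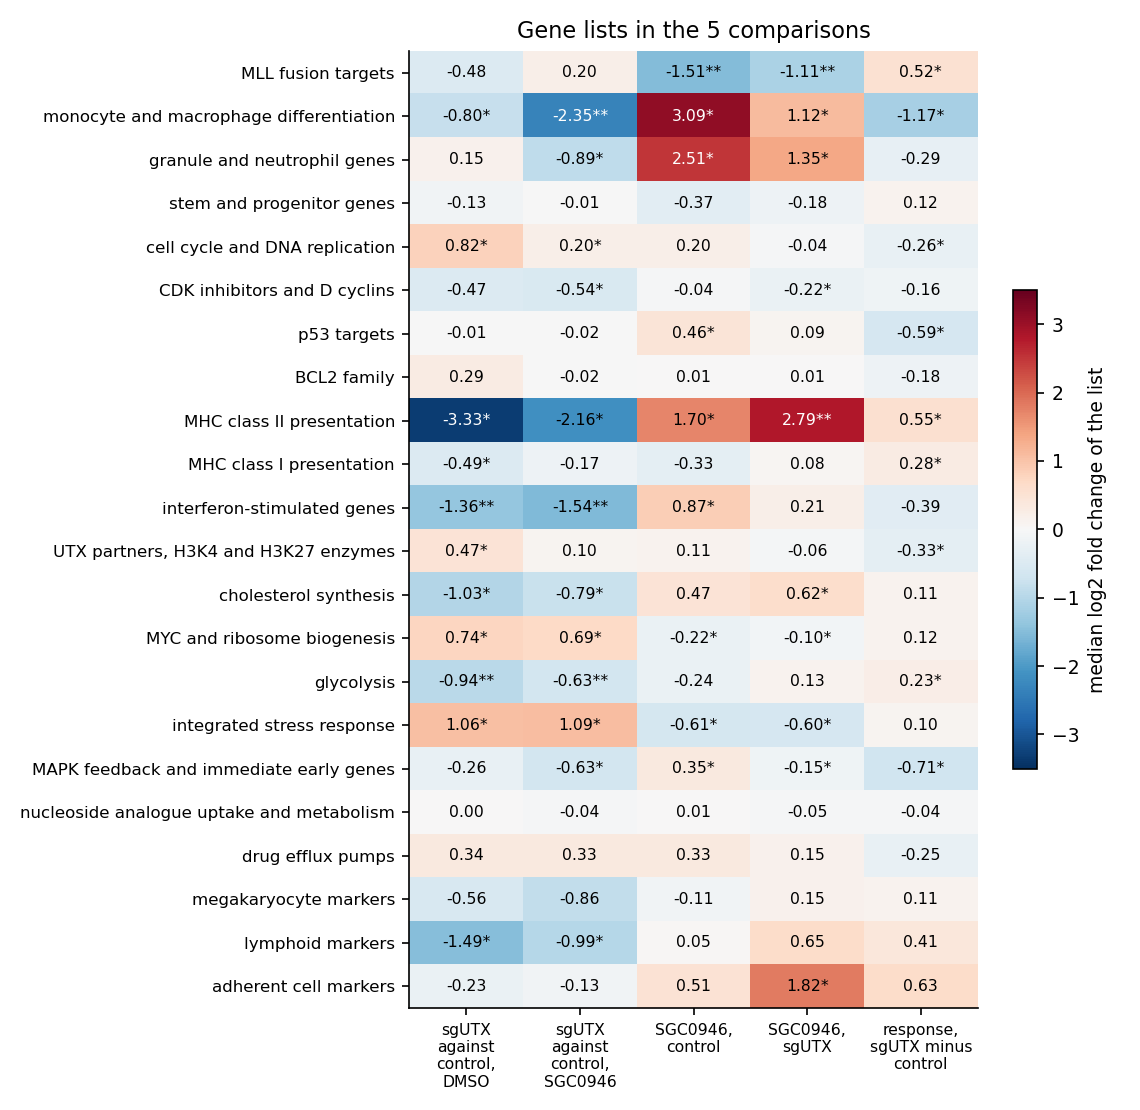
Median log2 fold change of each of the 22 tested gene lists (rows of the grid) in the 5 comparisons (columns), by color and printed value. A star marks a camera adjusted p under 0.05 and 2 stars a call that also holds with an estimated correlation, as for MLL fusion targets with SGC0946 (-1.51 and -1.11), and no starred median changed sign with library size only or RLE factors.

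Some lists were called in none of the 5 comparisons, with lowest camera adjusted p of 0.126 for stem and progenitor genes (sgUTX response), 0.0796 for the BCL2 family (response difference), 0.0737 for nucleoside analogue genes (control response), 0.322 for drug efflux pumps (DMSO) and 0.399 for megakaryocyte markers (SGC0946). None of 8 HOXB cluster genes and 2 of 16 erythroid markers were measured, and these lists were not tested.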

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

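The count of splits of the samples was planned. The tests of gene length and GC content, chromosomes, control guides, response slopes, low counts, DMSO cultures and library scaling were chosen after the results they bear on were seen.

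KDM6A differed between the sgUTX_4 and sgUTX_2 libraries by 1.66 in DMSO and 1.6 with SGC0946 (log2, edgeR adjusted p = 7.05e-14 and 1.6e-13). The response to SGC0946 differed between sgUTX and control libraries for 5240 genes by the interaction test. For 575 genes the responses were called in opposite directions, 324 rising in control and falling in sgUTX libraries and 251 the reverse. CDKN1A was among them, with a response difference of -2.81 (SE 0.15, adjusted p = 5.7e-12). Calls in the same direction were more numerous, 1540 rises and 1238 falls in both, so the opposite calls show no general reversal. How many opposite calls independent lists would give was not computed.

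Among 162 pairs of a named gene and a group of 4 sgUTX libraries, 6 had a library far from the other 3, where chance gives about 8. The gap took these shares of the group's range. In DMSO it was 1 for PNCK in the second sgUTX_2 library, the only library of the 4 with counts, 0.948 for IDI1 and 0.855 for FGL2 in the first sgUTX_4 library, and 0.837 for RUNX2 in the first sgUTX_2 library. In SGC0946 it was 0.838 for SLC7A2 and 0.889 for CCND3 in the second sgUTX_2 library. A large share can be a small gap: CCND3 stood at 398 CPM there, against 389 to 390 in the other 3 libraries.

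The sgUTX and control DMSO libraries differed in 9188 of 15060 genes. Gene length and GC content, in deciles, explained 2.45% of the variance of the log2 fold change, and the chromosome of the gene 0.496%. This argues against either as the direct source of most of the difference. Gain or loss of a single chromosome or chromosome part, or its effects on genes elsewhere, would hardly show in these shares and stays open. A difference of the single control population from the sgUTX populations, not due to the guide target, cannot be told apart from an effect of the guides, because the design has 1 control guide and no rescued population. Loss of UTX may be the cause, and KDM6A levels that moved in opposite directions with the 2 guides leave that untested at the protein level.

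Of 23 monocyte genes 11 had a lower and 1 a higher response to SGC0946 in sgUTX than in control libraries (camera adjusted p = 8.98e-07; adjusted p = 0.156 with an estimated correlation, so the list call depends on the preset one). A uniformly weaker action of SGC0946 would scale all responses alike. The slope of the sgUTX on the control response was 0.701 for MLL fusion targets and 0.454 for monocyte genes. The difference was 0.247 (95% bootstrap interval 0.0255 to 0.562, which treats genes as independent). The estimated correlation among monocyte genes was 0.34 for the response difference, so this interval is too narrow to decide on uniform scaling. A weaker action with a steeper effect on monocyte genes stays open as well. Low counts in the sgUTX libraries stay open, since 6 of 15 monocyte genes with a mean of at least 10 CPM there were called, no more than the binomial limit of 6 for the share of all genes with a lower response. That mean covers both treatments, so the sgUTX response itself helped to decide which genes entered, and this count cannot settle the point. A dependence of the monocyte response on UTX may account for the pattern, with the single control population left open. For the response itself, 1 of the 35 splits of the 8 sgUTX libraries, the real one, called as many genes (4559). The highest other split, by guide, called 7. This met the planned criterion against a random grouping of these 8 libraries. It cannot exclude chance between cultures, since libraries of a group may be technical and other splits put the treatment effect into the error.

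The 20 glycolysis genes, a list set before the data were examined, had a median log2 fold change of -0.94 in sgUTX against control DMSO libraries, with 17 lower and 1 higher. Its 95% bootstrap interval over genes, not libraries, was -1.33 to -0.62, and the intervals below are of the same kind. With TMM scaling, the state of the DMSO-treated control cultures alone is argued against by a median of -0.63 (-0.85 to -0.51) in SGC0946, where 17 were lower. With library size only the SGC0946 median was -0.44, with 16 lower and 2 higher, which lies between the bounds set for this test. The verdict on the DMSO cultures therefore depends on the scaling. Library scaling as the whole cause is argued against by a DMSO median of -0.66 (-1.06 to -0.34) with library size only, which moved the median of all genes from -0.01 to 0.26 and left 15 lower and 1 higher. The bound for scaling, -0.25, and the bounds for the DMSO cultures were set after these values were seen, and a part of the size stays open to scaling. Of 17 low-oxygen response genes, chosen after their values were seen, 16 were lower in DMSO and 14 in SGC0946 (medians -1.8 and -1.1; adjusted p = 0.0022 and 0.0076 with an estimated correlation). Because of that choice, these p-values are descriptive and do not test the list. Denser or less aerated control cultures in both treatments may give the same pattern, which culture measurements would be needed to test, and an effect of UTX guides on these genes stays open as a hypothesis.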

How the results depend on the processing

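The scaling on genes other than ribosomal protein, histone and mitochondrial genes was chosen after the data were seen, and all other alternatives were planned. Of 183 combinations of a named gene other than KDM6A and a comparison, 181 kept direction and call under every alternative that tested them. The 2-fold threshold was not among these alternatives. Some combinations of VNN2, LILRA5 and LILRB3 were tested under fewer alternatives than the other genes of their comparison. KDM6B in DMSO lost its call with library size only (-0.15, adjusted p = 0.0578), and FCN1 in the response difference lost it without the first or second control DMSO library or the second control SGC0946 library (largest adjusted p = 0.0911). The cause was not tested. A threshold of 2-fold left 3067 genes for sgUTX against control in DMSO, 2206 and 1116 for SGC0946 in control and sgUTX cells, 2594 for sgUTX against control in SGC0946 and 1334 for the response difference, because it removes smaller changes. Leaving out 1 library gave 7773 to 9241, 5820 to 7526, 4448 to 5035, 6822 to 8702 and 3928 to 5264 genes. Where a group then held 1 library, that library was assumed to vary like the other groups. The counts between guides ranged from 89 (without the first sgUTX_4 library) to 694 in DMSO, with 274 without the second sgUTX_2 library, and from 90 (without the first sgUTX_4 library) to 617 with SGC0946, with 102 and 283 without the first or second sgUTX_2 library. DESeq2 called 8851, 6891, 4897, 8063 and 4951 genes, and the added scaling 9190, 7365, 5090, 8561 and 5255. KDM6A in DMSO stood at -0.160 with 6 groups averaged, -0.988 with sgUTX_2 alone, 0.656 with sgUTX_4 alone, and between -0.254 and 0.290 over the leave-one-out fits, because the guides went in opposite directions. With camera and an estimated correlation 2, 1, 2, 3 and 0 lists were called in the 5 comparisons, against 11, 9, 10, 12 and 9 with the preset one, and fry, which does not compare a list with other genes, called 19, 20, 19, 21 and 15. The fit with the replicate number as a block called 9072, 7206, 4909, 8400 and 5035 genes, and lost 1 and gained 1 list call. Replicate numbers share only a number: of 15 pairs of groups, correlations of same-numbered deviations lay between -0.238 and 0.135, and 1 was above 0.1. Depth limited genes with few counts in a group, among them JPH2 and PNCK with 6 counts over 4 sgUTX DMSO libraries.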

Other observations

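The gene families and genes in this part, and the list tests between guides, were chosen after their values were seen, so the p-values here are descriptive only. In DMSO, all 5 measured metallothionein genes, which bind zinc and copper, were lower in sgUTX than in control libraries (median log2 fold change -3.82, camera adjusted p = 5.7e-10; adjusted p = 0.004 with an estimated correlation). The 8 Fc receptor genes chosen, which are not all genes of that class, were lower as well (median -2.22, adjusted p = 0.004 with an estimated correlation). Of 17 low-oxygen response genes 16 were lower (median -1.8; adjusted p = 0.0022 with an estimated correlation). Histone genes were lower in 26 of 28 (median -3.18, camera adjusted p = 2e-06; adjusted p = 0.26 with an estimated correlation), and cytoplasmic ribosomal protein genes lower in 73 and higher in 4 of 83 (median -0.9; adjusted p = 0.085 with an estimated correlation). Many histone genes stood under 1 CPM in sgUTX DMSO libraries, some with wide errors, such as HIST1H3B (0.313 CPM, SE 1.29). A better counted one, HIST1H1C, went from 38.5 to 3.76 CPM (-3.35, SE 0.17). Between sgUTX and control SGC0946 libraries, histone genes were lower in only 9 of 28 (median -0.85; adjusted p = 0.53 with an estimated correlation). Metallothionein genes were lower there in 4 of 5 (median -1.48; adjusted p = 0.059 with an estimated correlation) and Fc receptor genes in all 8 (median -2.78). Ribosomal protein genes also fell after SGC0946 in control cells in 70 of 83, against none in sgUTX cells, where 3 rose. Their response difference was higher in 65 (adjusted p = 0.19 and 0.15 with an estimated correlation for control response and response difference). The control DMSO libraries enter the DMSO comparison, the control response and the response difference. Between sgUTX and control SGC0946 libraries, where they do not enter, 65 of 83 were lower and 6 higher (median -0.33, camera adjusted p = 0.00091; adjusted p = 0.53 with an estimated correlation). In DMSO, 11 of 12 chosen cytosolic tRNA synthetase genes, a part of that family, were higher in sgUTX than in control libraries (median 0.77; adjusted p = 0.22 with an estimated correlation). The signs of these medians held with library size only and with RLE factors. After SGC0946 in control cells, toll-like receptor genes rose in 7 of 8 (median 2.69) and LILR genes in 6 of 8 (median 2.83, 1 fell), both with an adjusted p of 0.00053 with an estimated correlation.

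Between the guides, granule and monocyte genes were higher with sgUTX_4 than with sgUTX_2. Granule and neutrophil genes were higher in 8 of 17 in DMSO (camera adjusted p = 8.9e-27; adjusted p = 0.0086 with an estimated correlation) and in 10 of 17 with SGC0946 (adjusted p = 0.0046 with an estimated correlation). Monocyte and macrophage differentiation genes were higher in 8 of 23 in DMSO (adjusted p = 0.0039 with an estimated correlation) and in 6 of 23 with SGC0946 (adjusted p = 0.0046 with an estimated correlation). The neutrophil elastase gene ELANE was higher by 0.9 in DMSO and 0.7 with SGC0946, FCN1 by 2.05 and 1.5 and the chemokine receptor CCR2 by 1.5 and 0.75. In both treatments 145 genes differed in the same direction, where independent lists would share 4 higher and 4 lower, and the 2 treatments share no library. Leaving out 1 sgUTX library gave 46 (without the first sgUTX_2 SGC0946 library) to 216 shared genes (without the second sgUTX_4 DMSO library), so this count depends on single libraries. Granule genes were then higher in 6 to 9 in DMSO and 6 to 12 with SGC0946 and monocyte genes in 4 to 9 and 5 to 9, each list with an adjusted p of at most 0.036 with an estimated correlation.

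Among genes whose responses to SGC0946 were called in opposite directions, TNF rose by 2.11 in control and fell by 1.28 in sgUTX libraries (difference -3.39, SE 0.4), CR1 rose by 1.49 and fell by 1.44, TRIB1 rose by 2.13 and fell by 0.57, and G0S2 rose by 1.19 and fell by 1.44. PPP1R1B fell by 1.26 and rose by 2.19, TENT5C fell by 2.15 and rose by 0.78, and the metallothionein gene MT1X fell by 2.05 and rose by 0.68.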
